A study of Mus musculus with 9 samples.

How the data were processed

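The 9 libraries hold RNA from nucleus accumbens cells of male C57BL/6 mice. Per the labels, mice of the RES and SUS groups first took up to 40 cocaine infusions under a fixed ratio schedule and then had 10 daily progressive ratio sessions of 23 h, in which each further infusion of 1.2 mg/kg costs more responses. Tissue was taken on day 3 after the last session, after perfusion with saline. Punches of 2 to 3 mice per condition were pooled, dissociated with papain in a medium containing DNase I, labelled with a fluorescent antibody against ChAT and sorted. The labels do not say whether the libraries of a group came from separate pools, so the p-values measure only the spread between these libraries.

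Groups follow the sample titles. For the RES libraries the behavioural phenotype field says susceptible and for the SUS libraries it says resilient, which conflicts with the titles, and nothing in the labels settles it. The drug-naive libraries carry the same description in both places.

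The deposited table holds raw counts of 52636 Ensembl mouse genes in 9 columns, whole numbers with different column totals and no scaling. The authors' processing notes name FastQC, STAR 2.5.2b, HTSeq, DESeq and DESeq2 and the build GRCm38, without their order or settings, and the strand setting and annotation release are not stated in the sources used here. Gene positions, exonic lengths and symbols came from GENCODE mouse release 21 (52489 of the IDs) and a table of gene names (52403 of the IDs), and 147 IDs matched neither. The 36 pairs of libraries had Spearman correlations of 0.864 to 0.961 across genes, and replicates of 1 group 0.874 to 0.951.

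Total counts ran from 4471675 to 11155730 per library. Mitochondrial genes took 9.09% to 28.7% of counts, mostly the ribosomal RNAs mt-Rnr2 and mt-Rnr1, and the 5 most counted genes together 17.8% to 35.1%. Scaling factors by the trimmed mean of M values (TMM) ran from 0.743 to 1.58, the highest in RES replicate 3. Background was defined as the summed counts of 1092 olfactory receptor genes per kb of their exons, and each gene's own count density was divided by it. The log2 scale has the median standard error 0.352 per gene for RES against naive, 0.345 for SUS against naive, 0.346 for SUS against RES and 0.303 for cocaine against naive.

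Genes were filtered with filterByExpr, scaled by TMM and tested with the edgeR quasi-likelihood F test (edgeR 4.0.16, limma 3.58.1, R 4.3.3), with Benjamini-Hochberg adjustment at 0.05. The 3 pairwise comparisons came from 1 model of 3 groups, and cocaine against naive from a model of 2 groups. Standard errors were derived from the fold change and its F statistic. CPM values are scaled by TMM. Other tools were DESeq2 1.42.0 and limma-voom with sample quality weights. For 36 gene lists, covering neuronal function, signalling, stress, metabolism and markers of accumbens and blood cells (771 entries, 2 of them not among the gene symbols of the table), camera of limma was run on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 36 lists. Camera with an estimated correlation and fry were run beside it. Camera asks whether a list ranks above or below the other genes, and fry whether its genes move one way on balance. The gene lists, the tests and the rule for naming genes were fixed before the data were examined. List scores, the mean log2 CPM per library, were compared by two-sided exact permutation tests, which cannot go below p = 0.1 with 3 against 3 libraries or 0.0119 with 6 against 3.

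Named genes followed a rule. It took up to 10 genes each way that passed the test, with at least 10 CPM in a group and no overlap between the groups. As fewer than 5 passed, it took the 5 with the smallest p each way under the same conditions on level and overlap, leaving out predicted genes and olfactory or vomeronasal receptors. It always took Chat, Slc18a3, Slc5a7, Drd2, Drd5, Chrm2 and Fos, and up to 4 members of each list by smallest p. Of the list members, the text gives mainly the 2 with the smallest p in the 6 lists with the smallest camera p per comparison, a narrowing chosen after the values were seen.

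The test was tried on simulated data with 200 changed genes among libraries of the same depth and spread. For RES against naive it recovered 0% of 2-fold, 68% of 4-fold and 89% of 8-fold changes, and among genes of at least 10 CPM 0.5%, 89% and 99.5%. For cocaine against naive the shares at 2-fold and 4-fold were 2.5% and 87%, and 16% and 97% among genes of at least 10 CPM. With no changed genes it called 0 genes in each of the 4 comparisons. A ribosomal list lowered 1.5-fold in simulated data was called by camera at adjusted p = 1.55e-10 with the preset correlation and 0.00372 with an estimated correlation. Genes were drawn independently in these simulations, so the list result does not show the power of camera on genes that move together. In the real libraries the ribosomal list had a median log2 fold change of 1.36 for SUS against RES. Its adjusted p by camera with an estimated correlation was 0.657.

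Alternatives were median-of-ratios and upper-quartile scaling, no filter, a filter of 10 CPM, robust dispersion, the other tools, fits of only the groups compared, the replicate number as a block and leaving out each library in turn. Others were added after the data were seen, namely genes above 3 times background alone, the microglial score as a covariate, and leaving out RES replicate 3 and SUS replicate 3 together. The correlation of RES and SUS fold changes was set beside 20 simulations without a group difference, as the naive libraries could not be split into parts of at least 2. All 9 libraries were used.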

Results

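RNA sequencing measured gene expression in cells sorted as cholinergic interneurons, the acetylcholine-releasing local neurons of the striatum, from the nucleus accumbens of male C57BL/6 mice. The cells were taken from dissociated tissue punches by fluorescence for an antibody against ChAT, the enzyme that makes acetylcholine, and tissue was pooled from 2 to 3 mice per condition, without a statement of whether each library had its own pool. The 9 libraries fell into 3 groups of 3, drug-naive mice and the groups titled RES and SUS, which had self-administered cocaine at 1.2 mg/kg per infusion over 10 days of progressive ratio sessions. The titles and the behavioural phenotype field of the labels name RES and SUS in opposite ways, so the title names are kept and no difference is read as susceptible or resilient. Total counts over all genes were 6930527, 4471675 and 10667056 in naive replicates 1 to 3. They were 6895457, 4574518 and 4913649 in RES and 11155730, 8626317 and 8081639 in SUS.

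The genes that define cholinergic interneurons were near the level of genes that the brain does not express, while genes of medium spiny neurons, astrocytes and microglia stood above it to an extent that differed between libraries. That level, called background here, is the count density of 1092 olfactory receptor genes, which was 6.09 to 21.2 counts per exonic kb. Of the 17 genes of cholinergic identity, 0 averaged more than 3 times background, against 5751 of all 21883 protein-coding nuclear genes. Chat (ENSMUSG00000021919, chromosome 14, 32408203 to 32465989, GRCm38) was at 1.64, 1.54 and 1.92 times background in naive, 1.38, 2.5 and 1.88 in RES, and 1.27, 7.87 and 0.877 in SUS. Slc5a7, the choline transporter (chromosome 17, 54273590 to 54299034), was at 0.801 to 1.46 times background over the 9 libraries, and Slc18a3, the vesicular acetylcholine transporter (chromosome 14, 32462438 to 32464850), at 0.395 to 2.29. The list of medium spiny neurons was at a median of 2.69 (RES replicate 3) to 9.28 times background, that of astrocytes at 3.42 to 15.9 and that of microglia at 1.98 to 52.2. Genes restricted to other tissues had a median of 1.57 to 2.09 times background for 40 autosomal genes and 0.675 to 0.819 for 22 X-linked genes. Background is thus a low floor for autosomal genes. In RES replicate 2 the autosomal value, 2.09, exceeded the 1.98 of the microglial list, which was not above silent genes there. In the same libraries the medium spiny neuron gene Ppp1r1b was at 4.12 to 20.4 times background and the astrocyte glutamate transporter Slc1a2 at 11.6 to 90.5. The microglial receptor Cx3cr1 ranged from 1.44 to 68.9, and it was above 20 times background in naive replicates 1 and 2, RES replicate 1 and SUS replicates 1 and 3. Between 23.8% and 50.4% of the counts on nuclear genes were at the density of background, the highest share being in RES replicate 3. As silent autosomal genes lay above that density, the share would be larger at their level. The mean log2 CPM of the cholinergic identity list did not separate the groups, with a difference from naive of 0.03 in RES (exact permutation p = 0.9, two-sided). It was 0.05 lower in SUS than in RES (difference -0.05, exact permutation p = 0.8), a sign that turned without RES replicate 3 (0.01) or SUS replicate 3 (0.06).

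**Figure D1:**
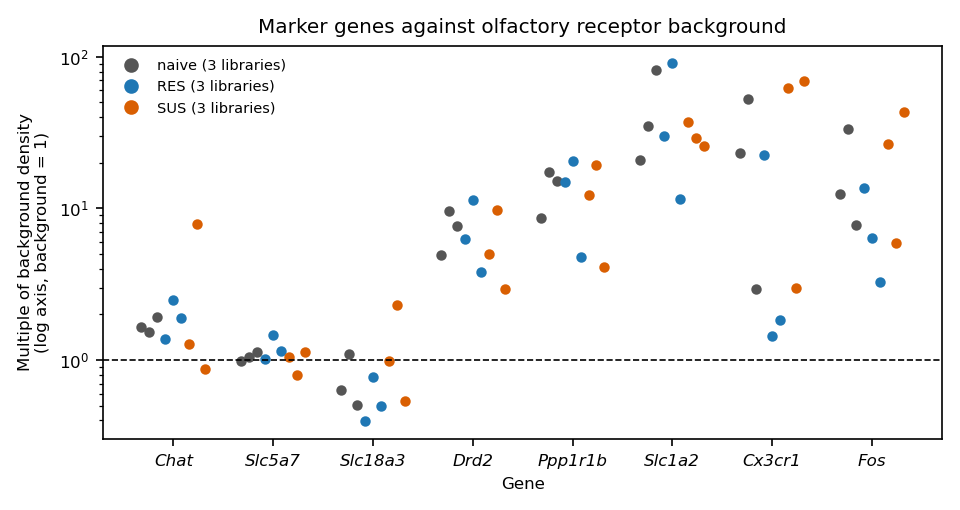
Multiples of background (counts per exonic kb over the density of olfactory receptor genes, log axis) of 8 marker genes, each point a library and the dashed line background itself. Chat, Slc5a7 and Slc18a3 lie near the line apart from Chat in SUS replicate 2 at 7.87, while Slc1a2 lies between 11.6 and 90.5.

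The comparison of RES with drug-naive libraries asked how the sorted cells differed in one of the groups that had taken cocaine. Genes of microglia, cytosolic ribosomes and the immediate early response were lower in RES as groups, and no single gene passed the test. All 18 microglial genes were lower (median log2 fold change -1.20), as were 70 of 71 cytosolic ribosomal protein genes (-0.75) and 25 of 27 immediate early genes (-0.92). Camera with a preset correlation called these 3 lists at adjusted p = 2.68e-07, 9.41e-19 and 4.15e-08, and each had an adjusted p = 0.825 with an estimated correlation. With 1 library left out the medians ran from -3.56 to -0.49, -1.57 to -0.28 and -1.49 to -0.27, and with the replicate number as a block the microglial median was -2.23. With the microglial score as a covariate, a fit added after the data were seen, none of these 3 lists was called. For the microglial list that follows from the score itself. The microglial genes Fcrls and Tmem119 averaged 30.3 ± 30.8 and 16.6 ± 21.2 CPM in RES (SD, n = 3) and 90.3 ± 73 and 52.9 ± 39.5 CPM in naive (n = 3). The ribosomal genes Rplp0 and Rpl27 averaged 31 ± 20.7 and 14.1 ± 7.31 CPM in RES and 65.2 ± 43.3 and 23 ± 7.89 CPM in naive. Klf2 and Klf4, transcription factors on the immediate early list, averaged 6.51 ± 5.9 and 19.2 ± 8.61 CPM in RES against 17.3 ± 10.9 and 39.2 ± 17.8 CPM in naive. Within RES, the microglial list was at a median of 15.9 times background in replicate 1, 1.98 in replicate 2 and 2.15 in replicate 3. Its mean log2 CPM was -1.55 relative to naive (exact permutation p = 0.2, two-sided, adjusted p = 0.953 over the 36 lists), where 0.1 is the smallest p that 3 against 3 libraries allow.

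A further 9 lists were lower in RES with the preset correlation. All 13 mitochondrially encoded genes were lower (median log2 fold change -0.47, adjusted p = 7.39e-06), with mt-Nd4l at -0.92 (SE 0.636) and mt-Atp6 at -0.81 (SE 0.563), and their median was -0.74 with the replicate number as a block. Genes of the unfolded protein response were lower in 18 of 20 cases (-0.42, adjusted p = 0.000244), among them the chaperone Calr at -0.96 (SE 0.573) and Creld2 at -0.44 (SE 0.283), and heat shock genes in 17 of 18 (-0.43, adjusted p = 0.000721). Genes of border and blood macrophages were lower in 11 of 13 cases (-0.51, adjusted p = 0.000244). Of these, the antigen presentation genes Cd74 (-1.43, SE 0.593) and H2-Ab1 (-0.99, SE 0.424) were lower in all 3 RES libraries than in any naive library. Oligodendrocyte genes were lower in 15 of 16 cases (-0.48, adjusted p = 0.00371) and those of their precursors in 11 of 11 (-0.44, adjusted p = 0.0011). Chromatin regulators (31 of 34 lower, -0.20, adjusted p = 0.000518), nuclear genes of oxidative phosphorylation (42 of 59, -0.19, adjusted p = 0.00188) and cholesterol synthesis genes (17 of 20, -0.14, adjusted p = 0.0236) made up the rest. With all libraries the red blood cell list was the only one of the 36 called higher in RES (4 of 6 genes higher, median 0.22, adjusted p = 0.0213). Each of these calls had an adjusted p of 0.825 or 0.848 with an estimated correlation. The number of lists called, 13, depended on single libraries and was 20 without naive replicate 1, 5 without naive replicate 2 and 23 without RES replicate 2. The microglial, ribosomal, immediate early and macrophage lists were called in every set with 1 library left out. Without RES replicate 3 none of the other 9 was called, the smallest adjusted p among them being 0.132 for the unfolded protein response, and the medians of chromatin regulators, nuclear oxidative phosphorylation and red blood cells turned. The 10 calls without that library were 4 lower and 6 higher, the latter being glutamate receptors, postsynaptic scaffold, GABA signalling, presynaptic release, cAMP and MAPK signalling and medium spiny neurons. Without RES replicate 3 and SUS replicate 3 together, a set chosen after seeing the data, 5 of 9 calls were higher. With 1 library left out the medians ran from -0.40 to 0.00 for cholesterol synthesis, -0.42 to 0.02 for chromatin regulators, -0.32 to 0.09 for nuclear oxidative phosphorylation and -1.53 to -0.02 for mitochondrially encoded genes. They ran from -0.76 to -0.02 for heat shock, -0.61 to -0.19 for the unfolded protein response, -0.78 to -0.20 for oligodendrocytes, -0.78 to -0.19 for their precursors, -0.68 to -0.26 for macrophages and -0.05 to 0.23 for red blood cells. Without naive replicate 2, of the 9 lists lost without RES replicate 3 only the mitochondrially encoded list was called. The cholesterol synthesis and red blood cell calls were also lost without RES replicate 1 or naive replicate 3, and the red blood cell call without SUS replicate 2 or 3, which enter through the shared spread.

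By the edgeR quasi-likelihood test, 0 of 39210 genes differed between RES and naive, 361 had an unadjusted p under 0.05 where chance gives 1960, and the smallest adjusted p was 1. DESeq2 and limma-voom with sample weights also called 0 genes, with 264 and 1671 at an unadjusted p under 0.05. None of the genes named next passed. Among genes of at least 10 CPM whose libraries did not overlap, the smallest p-values among those higher in RES belonged to Parpbp, Skint4, Lhcgr, Psg18 and Skint6. Parpbp averaged 10.2 ± 2.77 CPM in RES (SD, n = 3) and 5.96 ± 0.72 in naive, a log2 fold change of 0.76 (SE 0.258), and Lhcgr, the luteinizing hormone receptor, 12 ± 2.38 against 7.42 ± 1.06 CPM. Skint4, Psg18 and Skint6 had log2 fold changes of 0.70, 0.60 and 0.54. The smallest p-values among those lower in RES belonged to Calml4 (-0.74, SE 0.234), the sphingosine kinase Sphk1 (-0.76, SE 0.27), the nuclear receptor Nr5a1 (-0.71, SE 0.254), Lgals3bp (-0.91, SE 0.358) and Kctd10 (-0.64, SE 0.254). Lgals3bp, a secreted galectin-binding protein, was at 4.78 times background and averaged 14.2 ± 4.35 CPM in RES against 26.7 ± 6.28 in naive. Of these 10 separated genes only Lgals3bp averaged over 3 times background. Non-overlapping libraries were found for 1.82% (higher) and 2.27% (lower) of the 14980 genes of at least 10 CPM, where chance gives 5% each way. Chat had a log2 fold change of 0.18 (SE 0.57), Slc18a3 -0.32 (SE 0.492), Slc5a7 0.22 (SE 0.228), the dopamine receptors Drd2 -0.03 (SE 0.382) and Drd5 0.76 (SE 0.608), the muscarinic receptor Chrm2 0.46 (SE 0.243) and Fos -1.08 (SE 0.677). Drd5 was at 0.265 times background, Chrm2 at 0.919, Drd2 at 6.82 and Fos at 17.

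The comparison of SUS with drug-naive libraries asked the same of the other group that had taken cocaine. The 2 hemoglobin genes Hbb-bs and Hba-a1 were higher in every SUS library than in any naive library, and ribosomal protein genes as a group were called higher and pan-neuronal genes lower with the preset correlation only. Both lists had an adjusted p = 0.915 with an estimated correlation, and 0 lists were called without SUS replicate 1 or naive replicate 3. Hbb-bs, the beta-globin gene (ENSMUSG00000052305, chromosome 7, 103826534 to 103828096), averaged 6.15 ± 1.07 CPM in SUS (SD, n = 3) and 1.52 ± 0.0533 CPM in naive (n = 3). It rested on 52, 49 and 61 counts in SUS and 11, 5 and 17 in naive, a log2 fold change of 2.00 (SE 0.336). Its adjusted p was 1 by edgeR over all genes and 0.0579 by DESeq2, the smallest of any gene by DESeq2 in this comparison. Adjustment over single lists, used here and below, makes no allowance for the 36 lists or the 4 comparisons. By it 0, 2, 7 and 2 list members passed in RES against naive, SUS against naive, SUS against RES and cocaine against naive. Adjusted over the list alone, 2 of the 6 red blood cell genes passed, Hbb-bs and the alpha-globin gene Hba-a1 (2.51 ± 2.24 against 0.419 ± 0.128 CPM, log2 fold change 2.44, SE 0.72). The list was called by camera (5 of 6 genes higher, median log2 fold change 0.11, adjusted p = 0.0314), and had an adjusted p = 0.915 with an estimated correlation and 0.00153 in the test of fry for change in either direction, while Slc4a1 and Alas2 of the same list had log2 fold changes of -0.27 and 0.12. Hba-a1 averaged 0.849 times background (0.202 to 3.22 over the 9 libraries), with 5.09 CPM in SUS replicate 1 and 1.11 and 1.33 in the other 2. Hbb-bs was at 3.56 to 4.26 times background in the SUS libraries and 0.876 to 1.07 in the naive libraries. In RES it was at 1.7 to 1.86, above each naive library and below each SUS library.

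All 71 cytosolic ribosomal protein genes were higher in SUS than in naive (median log2 fold change 0.58, adjusted p = 0.000278 by camera), with Rps25 at 1.08 (SE 0.548). Of 59 nuclear oxidative phosphorylation genes, 51 were higher (0.14, adjusted p = 0.0415), among them the complex I subunits Ndufs6 (1.14, SE 0.368) and Ndufb3 (0.78, SE 0.36). Interferon response genes were higher in 17 of 24 cases (0.32, adjusted p = 0.0235), with Ifi44 at 15.7 ± 2.52 CPM in SUS (SD, n = 3) and 10.6 ± 1.47 CPM in naive, and Ifi35 at 3.79 ± 1.45 against 1.64 ± 0.114 CPM. Both genes lay at about background. Pan-neuronal genes were lower in 15 of 17 cases (-0.26, adjusted p = 0.0235), with the cytoskeletal genes Stmn2 at 19.4 ± 2.96 against 27.6 ± 3.37 CPM and Nefm at 40.6 ± 18.8 against 67.6 ± 17.8 CPM. Markers of cortical glutamatergic neurons were lower in 10 of 11 cases (-0.24, adjusted p = 0.0415), including Neurod1 (-0.67, SE 0.315) and Slc17a6 (-0.46, SE 0.246), with 1 of the 11 above 3 times background. All 6 lists called here had an adjusted p = 0.915 with an estimated correlation. With the microglial score as a covariate, a fit added after the data were seen, 3 lists were called and all 3 were higher. The pan-neuronal and cortical glutamatergic lists were thus not called lower there. The microglial list was higher in SUS but not called (median 0.84, adjusted p = 0.145), and stood at 36.2, 3.26 and 52.2 times background in SUS replicates 1 to 3 and 17.5, 34.7 and 3.7 in naive. The 6 calls depended on single libraries, with 0 lists called without SUS replicate 1 or naive replicate 3, 3 without SUS replicate 3 or RES replicate 1, 18 without SUS replicate 2 (8 of them lower) and 12 without naive replicate 1 (9 lower). The ribosomal list had an adjusted p of 0.118 without SUS replicate 1, 0.896 without SUS replicate 3 and 0.846 without naive replicate 3. The pan-neuronal list had 0.774 without SUS replicate 3 and 0.202 without naive replicate 2. Without naive replicate 1 the nuclear oxidative phosphorylation list had 0.831 (median 0.015) and the cortical glutamatergic list 0.0905. The former was also lost without SUS replicate 3 (0.774), RES replicate 1 (0.0569) or RES replicate 2 (0.0525), and the latter without SUS replicate 2 (0.112), SUS replicate 3 (0.0963) or RES replicate 1 (0.0569). The red blood cell call held only without naive replicate 1 or SUS replicate 3, and its median ran from -0.018 without naive replicate 2 to 0.277 without naive replicate 1. The pan-neuronal median ran from -0.627 without SUS replicate 2, and was -0.444 without naive replicate 1, to 0.01 without SUS replicate 3. The ribosomal median ran from 0.095 to 1.06, that of nuclear oxidative phosphorylation from 0.015 to 0.257 and that of the interferon response from 0.203 to 0.427.

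Across all genes, edgeR called 0 of 39210 between SUS and naive, with 1225 at an unadjusted p under 0.05 (669 higher, 556 lower) where chance gives 1960, and a smallest adjusted p of 1. DESeq2 and limma-voom with sample weights also called 0, with 931 and 3225 at an unadjusted p under 0.05. None of the following genes passed. Hacd4, an enzyme of fatty acid elongation, averaged 17.8 ± 3.58 CPM in SUS (SD, n = 3) and 10.4 ± 0.371 in naive (log2 fold change 0.77, SE 0.221), at 1.01 times background. Zfp958 (0.83), Klhl35 (0.77), Lipo3 (0.73) and Ypel1 (0.78) were the other 4 with the smallest p-values among separated genes higher in SUS. Agr2, a disulfide isomerase of secretory cells, averaged 5.55 ± 0.973 CPM in SUS and 11.5 ± 2.09 in naive (log2 fold change -1.03, SE 0.251), at 3.37 times background. Igsf23 (-0.90), Ccdc170 (-0.79), Endou (-0.73) and Hapln3 (-0.89) followed among those lower in SUS. Among all these separated genes only Agr2 averaged over 3 times background. Of 15242 genes of at least 10 CPM, 3.59% were separated and higher and 2.83% separated and lower, where chance gives 5% each way. Chat had a log2 fold change of 0.97 (SE 0.562), which rested on 73.5 CPM in SUS replicate 2 and was -0.63 without that library. Slc18a3, also highest in that library at 11 CPM, was at 0.89 (SE 0.449), Slc5a7 at -0.04 (SE 0.226), Drd2 at -0.27 (SE 0.381), Drd5 at 0.35 (SE 0.6), Chrm2 at 0.39 (SE 0.24) and Fos at 0.65 (SE 0.667), the last being -0.10 without SUS replicate 3.

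**Figure D2:**
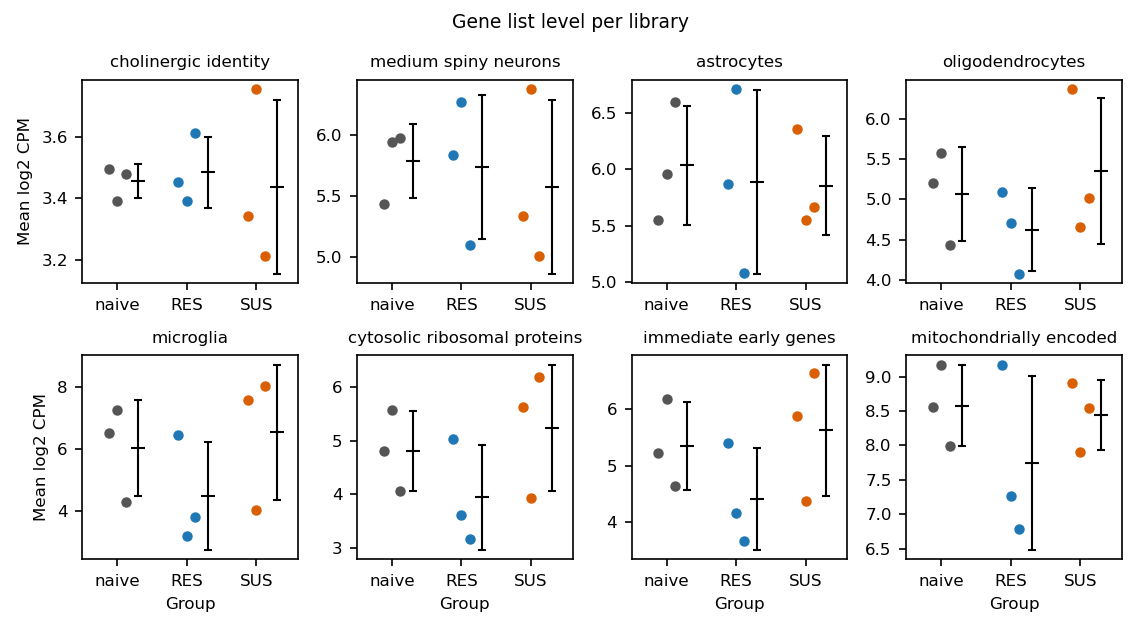
Mean log2 CPM of 8 gene lists in each library, with the group mean and SD (n = 3). The microglial list spans 3.18 to 8.03 over the 9 libraries, and in each group its libraries lie far apart.

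SUS was then compared directly with RES, the groups separated by their cocaine-taking behaviour, with higher microglial, ribosomal and immediate early genes in SUS. Microglial genes were higher in SUS in 18 of 18 cases (median log2 fold change 2.09), cytosolic ribosomal genes in 71 of 71 (1.36) and immediate early genes in 24 of 27 (1.65). Camera with the preset correlation gave adjusted p = 1.41e-08, 1.12e-26 and 6.46e-09, and each of the 3 lists had an adjusted p = 0.657 with an estimated correlation. With 1 library left out the medians ran from 1.48 to 4.47, 0.85 to 2.20 and 0.71 to 2.52. The microglial genes Sall1 and Tyrobp averaged 177 ± 123 and 42.2 ± 29.3 CPM in SUS (SD, n = 3) against 50.7 ± 28.8 and 13.5 ± 10.6 CPM in RES (n = 3). The ribosomal gene Rps20 averaged 40.7 ± 23.9 against 13.4 ± 8.29 CPM. The immediate early genes Jund and Ier3 averaged 20.7 ± 17.9 and 23.8 ± 16.7 CPM in SUS against 4.94 ± 2.58 and 6.39 ± 4.64 CPM in RES, and Fos 126 ± 101 against 38.1 ± 28.6 CPM (log2 fold change 1.73, SE 0.685). For all of these genes SUS replicate 2 lay among the RES libraries, with Fos at 27.7 CPM there and Sall1 at 35.3. In the exact permutation test the mean log2 CPM of the microglial list differed by 2.08 between SUS and RES (p = 0.2, adjusted p = 0.8 over the 36 lists), a design whose smallest p is 0.1.

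Other gene groups were higher in SUS than in RES with the preset correlation. Oligodendrocyte genes were higher in 15 of 16 cases (median log2 fold change 1.00, adjusted p = 0.000108), endothelial genes in 14 of 16 (0.45, adjusted p = 0.000895), and genes of border and blood macrophages in 11 of 13 (0.76, adjusted p = 0.000295). Adjusted over the list alone, 5 of the 13 macrophage genes passed, named here after their values were seen as Cd74 (log2 fold change 2.04), H2-Ab1 (1.42), H2-Aa (1.02), H2-Eb1 (0.90) and Lyz2 (1.93). Interferon response genes were higher in 22 of 24 cases (0.36, adjusted p = 6.18e-05), with Ifi27 at 18.3 ± 2.76 against 10.7 ± 1.73 CPM (SD, n = 3) and Irf1 at 53 ± 37.7 against 15.7 ± 10.9 CPM. Heat shock genes were higher in 18 of 18 (0.74, adjusted p = 0.000103), including the chaperones Hspa5 (1.54, SE 0.725) and Dnaja1 (0.95, SE 0.465), and unfolded protein response genes in 17 of 20 (0.56, adjusted p = 0.000108). Nuclear oxidative phosphorylation genes were higher in 54 of 59 cases (0.33, adjusted p = 1.17e-06), among them the cytochrome oxidase subunits Cox6a1 (0.92, SE 0.324) and Cox4i1 (0.93, SE 0.357), and mitochondrially encoded genes in 12 of 13 (0.44, adjusted p = 0.00139, median 0.70 with the replicate number as a block). Chromatin regulators (26 of 34, 0.15, adjusted p = 0.00551), cAMP and MAPK signalling (23 of 30, 0.23, adjusted p = 0.0137) and cholesterol synthesis (16 of 20, 0.19, adjusted p = 0.00975) were also higher. With all libraries and all genes, neuropeptides and opioid receptors were the only list called lower (14 of 21, -0.21, adjusted p = 0.0192). With an estimated correlation the adjusted p of these lists lay between 0.657 and 0.769. With the microglial score as a covariate, a fit added after the data were seen, the 15 calls of this comparison became 6. All 6 were higher, the ribosomal list among them, so most calls of this paragraph were lost there. The 15 calls became 9 without SUS replicate 1, where oligodendrocyte genes had an adjusted p of 0.43 and those of neuropeptides, chromatin, cAMP and MAPK signalling, mitochondrially encoded genes and cholesterol synthesis were lost as well. Without RES replicate 3 the lists of heat shock (0.118), nuclear oxidative phosphorylation (0.315), mitochondrially encoded genes and cholesterol synthesis (both 0.334) were lost, and those of chromatin regulators (0.604) and of cAMP and MAPK signalling (0.438) turned in direction. Of the 18 lists then called, 8 were higher and 10 lower in SUS, and without SUS replicate 2 there were 22 calls, 14 higher and 8 lower. On genes above background, a choice made after seeing the data, 8 were higher and 7 lower. Glutamate receptors, postsynaptic scaffold, GABA signalling, presynaptic release, pacemaking channels, medium spiny neurons and pan-neuronal genes were among the lower lists in all 3 of these. The endothelial call was lost without SUS replicate 3 (0.131), that of cAMP and MAPK signalling without SUS replicate 2, that of cholesterol synthesis without RES replicate 1, and that of neuropeptides without SUS replicate 3 or RES replicate 2. With 1 library left out the medians ran from 0.05 to 1.49 for mitochondrially encoded genes, 0.04 to 0.51 for cholesterol synthesis, -0.08 to 0.37 for chromatin regulators, -0.05 to 0.39 for cAMP and MAPK signalling and -0.41 to -0.07 for neuropeptides. They ran from 0.32 to 1.30 for oligodendrocytes, 0.11 to 0.53 for endothelium, 0.35 to 0.99 for macrophages, 0.32 to 1.21 for heat shock, 0.28 to 0.84 for the unfolded protein response and 0.12 to 0.46 for nuclear oxidative phosphorylation.

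edgeR called 0 of 39210 genes between SUS and RES, with 2227 at an unadjusted p under 0.05 (1571 higher, 656 lower) where chance gives 1960, and a smallest adjusted p of 0.87. DESeq2 and limma-voom with sample weights called 0, with 1885 and 3367 at an unadjusted p under 0.05. Lgals3bp, at 4.78 times background, averaged 41.1 ± 21 CPM in SUS (SD, n = 3) and 14.2 ± 4.35 in RES, a log2 fold change of 1.54 (SE 0.358) that did not pass. Abi3 averaged 14.5 ± 11.1 against 3.33 ± 1.06 CPM (2.09, SE 0.516), and Fhl3, a LIM domain protein, 12.3 ± 6.47 against 3.74 ± 1.62 CPM (1.67, SE 0.451). Etohd2 (0.97) and the collagen-binding Fmod (1.14) completed the 5 separated genes with the smallest p-values among those higher in SUS. Of these only Lgals3bp averaged over 3 times background, with Abi3 at 0.977, Fhl3 at 2.49, Etohd2 at 0.78 and Fmod at 1.85. Those lower in SUS were Psg18 (-0.81, SE 0.226), the lysyl oxidase Loxl2 (-0.89, SE 0.254), Endou (-0.72, SE 0.221), Styxl1 (-0.87, SE 0.292) and Rtl9 (-0.94, SE 0.315), none of which passed. Among them Psg18 averaged 1.61 times background, Loxl2 0.989 and Endou 2.07. Of 15345 genes of at least 10 CPM, 3.7% were separated and higher and 2.27% separated and lower, against 5% by chance each way. Chat was at 0.78 (SE 0.559), or -0.81 without SUS replicate 2, and Slc18a3 at 1.21 (SE 0.459). The Slc18a3 value leans on the same library, with 11 CPM in SUS replicate 2 against 4.66 and 2.9 in SUS replicates 1 and 3. Slc5a7 was at -0.25 (SE 0.225), Drd2 at -0.23 (SE 0.381), Drd5 at -0.41 (SE 0.569) and Chrm2 at -0.07 (SE 0.236). Adjusted over the list alone, Hltf of the p11 complex list (log2 fold change 1.03) and Hbb-bs of the red blood cell list (1.10, SE 0.314) passed, and these were named after their values were seen.

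**Figure D3:**
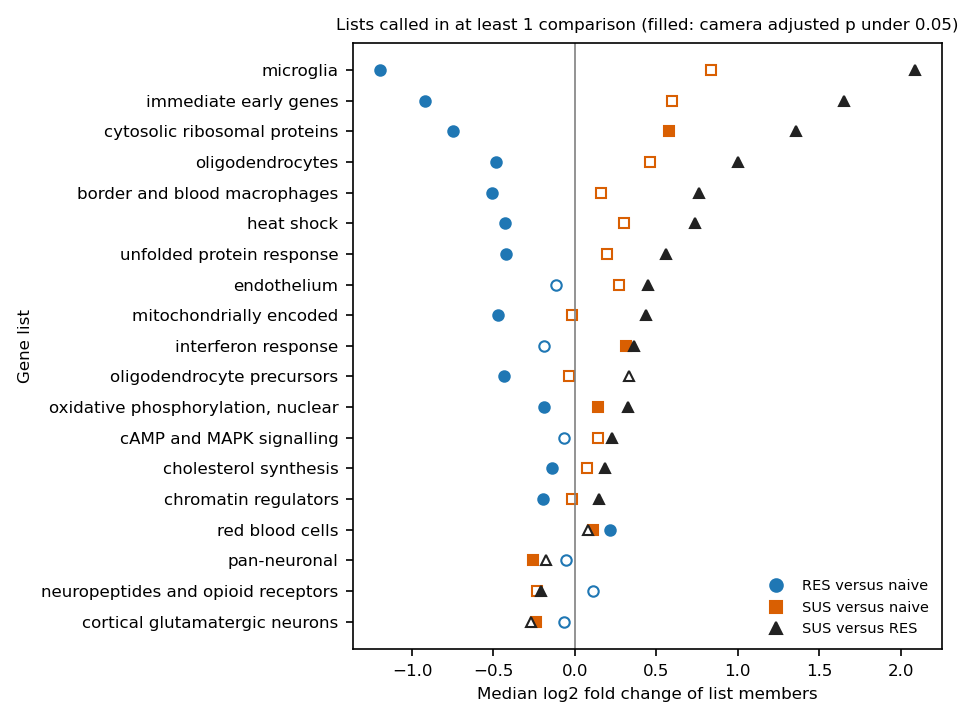
Median log2 fold change of the 19 gene lists called in at least 1 comparison, for the 3 pairwise comparisons, with filled points where the camera adjusted p with the preset correlation was under 0.05. Most lists lie below 0 for RES against naive and above 0 for SUS against RES.

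The 6 libraries from cocaine-taking mice were compared with the 3 drug-naive libraries, a comparison that does not depend on which of RES and SUS is the susceptible group. The 2 hemoglobin genes were higher in every cocaine library than in any naive library, and no gene list was called. Hbb-bs averaged 4.49 ± 1.95 CPM over the cocaine libraries (SD, n = 6) and 1.52 ± 0.0533 CPM over the naive libraries (n = 3), a log2 fold change of 1.58 (SE 0.406), and Hba-a1 1.9 ± 1.62 against 0.419 ± 0.128 CPM (2.08, SE 0.701). The separation of Hba-a1 rests on 0.644 CPM in RES replicate 2 against 0.555 in naive replicate 3, or 3 counts against 6, at an average of 0.849 times background. Adjusted over the list alone these 2 of 6 red blood cell genes passed, and over all genes their adjusted p was 1. The list as a whole had a camera adjusted p = 0.0648 (median 0.16), and its mean log2 CPM was 0.475 higher in the cocaine libraries (exact permutation p = 0.0238, adjusted p = 0.857 over the 36 lists). Mitochondrially encoded genes (median -0.22), pan-neuronal genes (-0.15) and oligodendrocyte precursor genes (-0.20) also had a camera adjusted p = 0.0648. Among their members, mt-Nd3 averaged 63.5 ± 64.9 against 124 ± 59.9 CPM, mt-Atp6 110 ± 70.2 against 146 ± 62.3, Nefm 46.1 ± 15.3 against 67.6 ± 17.8 and Stmn2 23.4 ± 5.46 against 27.6 ± 3.37 CPM. The count of 0 lists rested on single libraries, with 14 called without naive replicate 1, 7 without naive replicate 3, 5 without RES replicate 1, 11 without RES replicate 2, and 8, 6 and 7 without SUS replicates 1, 2 and 3. Nearly all of these calls were lower in cocaine, with 1 list higher without naive replicate 1, RES replicate 2 or SUS replicate 1 and 0 in the other sets.

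Among neuronal gene groups in the cocaine comparison, median log2 fold changes were -0.03 for acetylcholine receptors, 0.02 for dopamine signalling, -0.08 for glutamate receptors, -0.20 for the postsynaptic scaffold, -0.10 for presynaptic release, 0.01 for GABA signalling and -0.09 for pacemaking and excitability channels. They were -0.03 for cholinergic identity, -0.06 for medium spiny neurons, 0.05 for GABA interneurons, -0.12 for neurotrophins and their receptors, -0.12 for the circadian clock and 0.13 for the p11 complex. Among markers of other cells they were -0.13 for astrocytes, -0.09 for pericytes and smooth muscle, 0.07 for ependyma and choroid plexus and -0.10 for neutrophils. These 17 lists were called in 0 of the 4 comparisons with all libraries and all genes. Microglial (0.17), ribosomal (0.10) and immediate early genes (0.04) had positive medians while camera ranked them as lower than other genes (adjusted p = 0.165, 0.111 and 0.111). Median, mean and camera direction also differed in sign here for cholinergic identity, dopamine signalling, GABA signalling, cAMP and MAPK signalling, nuclear oxidative phosphorylation, cholesterol synthesis, oligodendrocytes and endothelium. They differed for the p11 complex and neutrophils in RES against naive and for cholinergic identity and dopamine signalling in both comparisons of SUS. They differed too for chromatin regulators, GABA interneurons and pericytes in SUS against naive, for the circadian clock and ependyma in SUS against RES, and for 0 of the lists called. C1ql1 and Neu4 of the oligodendrocyte precursor list had log2 fold changes of -0.47 (SE 0.378) and -0.31 (SE 0.274), the channels Kcnj2 and Kcnn1 0.30 (SE 0.248) and -0.20 (SE 0.179), and the chromatin regulators Hdac4 and Suv39h1 -0.40 (SE 0.248) and 0.35 (SE 0.25).

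By edgeR, 0 of 39210 genes differed between cocaine and naive libraries, 541 had an unadjusted p under 0.05 where chance gives 1960, and DESeq2 and limma-voom with sample weights called 0 with 484 and 1697. Pole2, a subunit of DNA polymerase epsilon, averaged 13.2 ± 0.713 CPM over the cocaine libraries (SD, n = 6) and 9.07 ± 0.811 over the naive libraries, a log2 fold change of 0.54 (SE 0.171) at 2.02 times background. Hacd4 (0.60), Skint6 (0.51), Skint4 (0.60) and Osgepl1 (0.55) were the other separated genes with the smallest p-values among those higher. Nr5a1 averaged 8.32 ± 1.68 against 13.3 ± 1.86 CPM (-0.66, SE 0.204), and Ccdc170 (-0.62), Samd11 (-0.58), Calml4 (-0.55) and Tex45 (-0.54) followed among those lower. None of these 10 passed, and all lay within 3 times background on average. Separated genes made up 0.387% (higher) and 0.307% (lower) of 14982 genes of at least 10 CPM, where chance gives 1.19% each way. Chat was at 0.64 (SE 0.528), or -0.10 without SUS replicate 2, Slc18a3 at 0.44 (SE 0.483), Slc5a7 at 0.09 (SE 0.197), Drd2 at -0.15 (SE 0.327), Drd5 at 0.56 (SE 0.525), Chrm2 at 0.42 (SE 0.204) and Fos at 0.03 (SE 0.684).

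Whether RES and SUS differed from naive in a shared way was read from their log2 fold changes across the 39210 genes, which are not independent replicates and use the same naive libraries. The correlation was 0.263, below the 0.501 to 0.518 of 20 simulations in which RES and SUS did not differ from naive. The covariance was 0.0365 against 0.0909 in those simulations, and 58.5% of genes had the same sign against 67%. Over the 5735 tested genes above 3 times background the correlation was -0.341, against 0.481 to 0.517 in the same simulations. The simulations drew each gene independently, while genes of the real libraries move together, so their range is too narrow to judge either value. Other splits of the libraries gave correlations over all genes from 0.0904 to 0.785, and the value of -0.341 was not set beside such splits. The correlation over all genes was 0.526 without naive replicate 1, 0.437 without naive replicate 3, 0.168 without RES replicate 1 and 0.156 without SUS replicate 2. Genes called in both comparisons numbered 0, as neither called any gene by edgeR.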

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

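The tests of the other cholinergic genes, of a short block of genes around Chat and of genes above background in every library were chosen only after the result was seen, and the fits with the microglial score as a covariate and on genes above 3 times background alone were added after the data were seen.

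Within the 6 cocaine libraries, 12 of 127 values tested had a highest or lowest library far from the rest by Dixon's 95% criterion, where about 1 in 20, or 6.35, come up by chance. SUS replicate 2 stood apart with Chat at 73.5 CPM (nearest library 20.3) and Slc18a3 at 11 CPM (nearest 4.66). SUS replicate 3 stood apart with Klf2 at 37.5 CPM (nearest 14.1), Klf4 at 108.5 (41.5), Jund at 40.3 (16.4), Ypel1 at 26.1 (17.1) and Fmod at 27.8 (13.8). SUS replicate 1 had Hba-a1 at 5.09 CPM (nearest 1.93) and RES replicate 2 had Kcnn1 at 18.3 CPM (nearest 14.9). RES replicate 3 had the lowest mean log2 CPM of chromatin regulators, 5.52 (nearest 6.30), and of cAMP and MAPK signalling genes, 4.90 (nearest 5.74), and the highest scaling factor, 1.58 (nearest 1.05).

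Chat was at 7.87 times background in SUS replicate 2, from 663 counts, and at 0.877 to 2.5 in the other 8 libraries. More cholinergic interneurons in that library is a possible explanation, but 3 of the 16 other cholinergic identity genes had their highest level there, where chance gives 1.8. These 3 were Isl1, Prima1 and Slc18a3, the last of which lies within Chat, while Slc5a7 had its lowest level there, 0.801 times background. As only 3 of the 16 exceed 3 times background in any library, the explanation cannot be told apart. Extra reads over the region were tested on the 23 genes within 500 kb, whose median ratio to the other libraries was 1.11 with 4 over 2, which met the bound set to exclude the explanation, but that bound was wrong for a block shorter than the window, as the raised genes adjoin each other. Ogdhl (3.66), 1700024G13Rik (6.58), Chat (4.96), Slc18a3 (3.93), Gm2990 (4.41) and Ercc6 (2.39) form 1 block of 259 kb on chromosome 14, 32322019 to 32580990, flanked by Parg at 1.16 and Prrxl1 at 0.89, and for the run of 5 genes from Ogdhl to Gm2990 the smallest ratio, with 0.1 added to each multiple, was 3.5, the highest of 42172 such runs in each of the 9 libraries (at most 2.5 in the others). Slc18a3 lies within Chat and Gm2990 starts inside it, and the strand setting is not stated. These genes are therefore not independent members of the run, while Ogdhl, 1700024G13Rik and Ercc6 lie outside Chat. Extra DNA or reads from this block may account for the Chat value, a hypothesis that leaves open what made the block and does not exclude a biological difference of that library.

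Microglial, ribosomal and immediate early genes were lower in RES and higher in SUS, with median log2 fold changes of 2.09, 1.36 and 1.65 for SUS against RES. On genes above 3 times background each kept at least 0.941 of its median, but that fit holds 17 of 18, 66 of 71 and 25 of 27 members and decides nothing, while a different share of background reads, which would shift all genes far above background alike, is argued against by the 1240 other genes above 3 times background in every library, with a median log2 fold change of 0 (quartiles -0.154 and 0.23) against 2.15, 1.31 and 1.78 for the 3, 15 and 4 members of that level. More carried-over microglia in some libraries is a possible cause of part of the pattern. With the microglial score as a covariate the ribosomal list kept 0.167 of its median (0.23, adjusted p = 0.000258 by camera). The immediate early list kept 0.117 (0.19, adjusted p = 0.0695 by camera). The score comes from the same libraries, over which the levels of the 3 lists rise and fall together. Any factor that they share would lower these medians too, so the fit cannot tell microglia from another shared factor. The ribosomal call did not end, but it came from camera with the preset correlation. Without the covariate, that test called 9 to 21 lists in the other splits of these 6 libraries. The remaining call therefore cannot tell whether carried-over microglia are the whole cause there. Although the sort for ChAT label should remove microglia, C1qa, an abundant microglial gene, was at 3.36 to 165 times background, and 0 of the 18 microglial genes are on another list. A difference between the behavioural groups in microglial number or state, or in what the dissociation induced, stays open and was not tested, as the microglial level differs within each group as well.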

How the results depend on the processing

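The genes above background alone, the microglial covariate, the fit without RES replicate 3 and SUS replicate 3 together, and the leave-one-out values of the cholinergic list were chosen after seeing the data. The count of genes called was 0 in all 4 comparisons under every alternative run, and leaving out each library in turn gave 0 to 0. For SUS against RES the smallest edgeR adjusted p came near the threshold without SUS replicate 2, at 0.0611 against 0.87 with all libraries. Genes at an unadjusted p under 0.05 then numbered 4712 against 2227. Simulated 2-fold changes were mostly missed (0% to 2.5% recovered, and up to 16% among genes of at least 10 CPM) and 4-fold changes mostly recovered (68% to 87% over all genes), so the 0 calls say little about changes near 2-fold. The simulated changes fell on randomly chosen genes. In the real data the 18 microglial genes had a median log2 fold change of 2.09 for SUS against RES, and 0 were called. The 0 calls therefore do not exclude 4-fold changes in genes as variable as these. Of 2058 values of 116 named genes and comparisons under the alternatives set in advance, 2030 kept their direction and side of the threshold, 28 in 16 of the 116 reversed, and 0 passed the threshold. Scaling moved the median of all genes by under 0.1 and turned the median of 0 of the called lists.

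Lists called, 13 for RES against naive, 6 for SUS against naive and 15 for SUS against RES, became 0 with an estimated correlation and 0 with the directional test of fry, whose test of change in either direction called 1 list, red blood cells in SUS against naive (adjusted p = 0.00153). Leaving out each library gave 5 to 23, 0 to 18 and 9 to 22, and 0 to 14 for cocaine against naive. Of the 13, 6 and 15, those higher numbered 1, 4 and 14. On genes above background the calls were 8, 12 and 15 (29 lists tested), of which 0, 3 and 8 were higher. With the microglial score as a covariate they were 12, 3 and 6 (1, 3 and 6 higher), and without RES replicate 3 and SUS replicate 3 they were 9, 3 and 7 (5, 3 and 5 higher). With that covariate the ribosomal and immediate early calls of RES against naive ended (adjusted p = 0.476 and 0.083 by camera). The microglial call ended too (0.904), which tests nothing, as the covariate is the mean of that list. For cocaine against naive, 0 at first, the lists called were 3 with the covariate and 5 with the replicate number as a block, 1 of each higher. The replicate numbers were not taken to pair the libraries. With each group's mean removed from log2 CPM, correlations between same-numbered libraries ran from -0.17 to 0.172, and 0 libraries had their best partner in another group under the same number. By the Spearman correlation of counts, which keeps what all libraries share, 3 of 9 had it, namely the replicates numbered 1 (0.958 to 0.961). The correlation of RES and SUS fold changes ran from 0.156 to 0.526 with 1 library left out.

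The following log2 fold changes reversed, and unless a left-out library is named the cause was not tested. With 1 library left out, Chat ran from -0.63 to 1.4 (SUS against naive), -0.81 to 1.22 (SUS against RES) and -0.10 to 0.81 (cocaine against naive), and Slc18a3 from -0.09 to 0.67 (cocaine) and Slc5a7 from -0.22 to 0.11 (SUS against naive), each crossing 0 without SUS replicate 2. Drd2 ran from -0.33 to 0.22 (RES against naive), -0.81 to 0.02 (SUS against naive), -0.77 to 0.06 (SUS against RES) and -0.32 to 0.01 (cocaine), Chrm2 from -0.27 to 0.03 (SUS against RES) and Drd5 from -0.16 to 0.73 (SUS against naive). Fos ran from -0.10 to 1.34 (SUS against naive) and -0.61 to 0.73 (cocaine), both lowest without SUS replicate 3. With voom sample weights Chat was at -0.01 (RES against naive), -0.08 and -0.06 (SUS against naive and RES), Drd5 at 0.07 (SUS against RES), Fos at -0.45 and Slc5a7 at -0.01 (cocaine). Fos in the cocaine comparison was at -0.29 with the block and -0.22 with the mean of both cocaine coefficients. For RES against naive, Drd2 was at 0.02 with upper-quartile scaling, 0.03 with the 10 CPM filter and 0.13 on genes above background. With the microglial covariate Chat was at -0.50 (RES against naive) and Drd2 at 0.02 (SUS against RES). Without both RES replicate 3 and SUS replicate 3, Drd2 was at 0.12 (cocaine), 0.21 (RES against naive) and 0.02 (SUS against naive), Fos at -0.38 (cocaine) and -0.10 (SUS against naive), and Slc5a7 at -0.03 (cocaine). The cholinergic list difference ran over -0.03 to 0.09 for RES against naive, -0.18 to 0.09 for SUS against naive, -0.21 to 0.06 for SUS against RES and -0.06 to 0.05 for cocaine, with 1 library left out, and turned its sign without RES replicate 3 (-0.03 and 0.01 for RES against naive and SUS against RES), SUS replicate 1 (0.02 for SUS against naive) and SUS replicate 3 (0.09 and 0.06 for SUS against naive and RES).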

Other observations

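The 3 tests of reads on silent genes and the counts of other splits were chosen before their results were seen, apart from the count of splits with as low a correlation, which was chosen after. The regression over silent genes also held a term for gene family that its description set in advance did not name.

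Genes of striatal projection neurons and of glia that no comparison above describes were also above background. Pde10a, the phosphodiesterase of medium spiny neurons, was at 3.79 to 28.4 times background, the GABA-synthesizing enzyme Gad1 at 2.93 to 9.84, the synaptic genes Snap25 and Syt1 at 2.61 to 9.58 and 3.8 to 15.6, and the dopamine receptor Drd1 at 1.2 to 5.34, above 3 in 3 of 9 libraries. The astrocyte transporter Slc1a3 was at 7.16 to 49.5 and the myelin gene Mbp at 2.51 to 20. The microglial gene P2ry12 was at 1.67 to 72.9, the immediate early gene Jun at 3.91 to 97.3 and Actb at 10.7 to 201. Pde10a was highest in RES replicate 2 and lowest in SUS replicate 3, and P2ry12 highest in SUS replicate 1 and lowest in RES replicate 2. Not every gene exceeded the autosomal genes restricted to other tissues in every library. P2ry12 was at 1.67 in RES replicate 2, where the median of those genes was 2.09, and Drd1 at 1.2 in SUS replicate 1, where it was 1.57.

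Reads fell on genes that the brain does not express in all 9 libraries, at 6.09 to 21.2 counts per exonic kb of olfactory receptor genes, and at that density they would make up 23.8% to 50.4% of the counts on nuclear genes. The share would be larger at the higher density of silent autosomal genes. Reads shared between near-identical gene copies were argued against, since 40 autosomal genes restricted to other tissues had a median density at least 1.57 times that of the olfactory receptors in every library. Genomic DNA in the libraries is a candidate source, since male mice carry a single X chromosome and its genes should then have 0.5 of the density. The plain ratio of 22 X-linked to 40 autosomal tissue-restricted genes was 0.384 to 0.522 and between 0.4 and 0.6 in 4 of 9 libraries, fewer than the 8 set in advance, so that test alone left it open. Adjusted for GC content, length and family (olfactory receptor or tissue-restricted) over 1154 genes, 28 of them X-linked, the X factor was 0.434 to 0.536. Its 95% interval included 0.5 and excluded 1 in 9 of 9 libraries. The family term was not part of the test as written in advance. With it the factor rests largely on the same tissue-restricted genes as the plain ratio, so the 2 tests are not independent. Relative to the olfactory receptors, the median of the X-linked tissue-restricted genes was 0.675 to 0.819. Genomic DNA thus stays a candidate although the medium held DNase I, and unspliced RNA from a low level of transcription was not tested.

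Other splits of the same libraries were counted beside each result. For RES against naive, SUS against naive and SUS against RES, the real split called 0 genes, the 10 splits of 6 libraries are too few for a share under 0.05, and the highest of the other splits called 0, 0 and 922 genes. The split with 922 genes set RES replicates 2 and 3 with SUS replicate 2, the 3 libraries low in microglial genes, against the other 3, which points to a structure of the samples other than the groups. For the lists, the real splits called 13, 6 and 15, the highest others 22, 20 and 21, and 7, 10 and 6 of the 10 splits called as many. For cocaine against naive the real split called 0 genes and 0 lists, which all 84 splits reach whatever they hold, so the count tests nothing there, and the highest others were 1445 genes and 22 lists. The split with 1445 genes set naive replicate 2, SUS replicate 1 and SUS replicate 3 against the rest. The correlation of RES and SUS fold changes, 0.263, lay below its simulated value, and 12 of 100 splits drawn from 840 had one as low (lowest other 0.0904), so chance is not excluded there. As high a correlation came from 89 of the 100, with 0.785 the highest other.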
